A study of Mus musculus with 24 samples.

How the data were processed

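Samples were mouse embryonic stem cell cultures in 24 libraries. There were 8 of the CLIP part (TET2 CLIP and input of clones 65 and 75, 2 replicates each), 4 of the RIP part (hm5C RIP and input, 2 replicates each) and 12 small RNA libraries (WT and Tet2 knockout of experiment 1, E14 and Tet2 knockout of experiment 2, 3 replicates each). Replicates were biological replicates per the series' design text, and groups followed the sample labels. Per the labels' protocols, RIP libraries and the small RNA libraries of experiment 1 were made with TruSeq kits, those of experiment 2 with NEBNext, and CLIP libraries with a custom protocol. Library kit, control line and knockout set therefore differed together between the 2 small RNA experiments.

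The deposited values were raw read counts, whole numbers with differing column sums. They covered 53900 features in the CLIP and RIP tables (435 tRNA genes and 53465 Ensembl genes, of which 191 had no symbol in the reference used here) and 1305 tRNA fragment features (1174 with any count) of 52 isoacceptors, 22 amino acids and 3 kinds. Per the submitters' processing notes, UMI-tools, cutadapt, STAR 2.5.3a and Bowtie2 2.2.6 were used with genome build mm10. The step each served, the counting tool, the annotation, the use of strand and the definition of the fragment kinds were not given in the sources used here. Coordinates and biotypes came from the RefSeq table for GRCm38.p6 (38184 features matched), the assembly of mm10, while the tRNA genes of the count tables were not matched to coordinates.

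Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, robust quasi-likelihood fit and F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. That filter keeps features with enough counts in as many libraries as the smallest group holds. Features scarce in a group thus entered only where another group was high. CLIP was fitted over 8 libraries with contrasts for both clones, each clone and the difference of clones, RIP over 4 libraries, and small RNA per experiment (6 libraries) and over 12 libraries with contrasts for both experiments and their difference. Means and SD are of CPM, counts scaled by library size and TMM factor, and log2 changes and SE come from the fit. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one. There were 24 lists in CLIP and RIP, with at least 3 tested members, and groups of fragments by kind, amino acid, isoacceptor, Trdmt1 substrates and retroviral primer tRNAs, with at least 5. Shares of fragment kinds were compared by exact permutation, and shared calls by Fisher's exact test.

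Genes and fragments were named by a rule. They were, per comparison, the 10 rising and 10 falling with the smallest p among called features whose libraries did not overlap, up to 4 members of each list with the smallest p, Tet2, and up to 10 fragments called in both experiments. Acsl6 and the isoacceptor sums were chosen after their values were seen. Some results the rule names are not reported here. The rule, the lists, the tests and most alternatives were fixed before the data were examined. Alternatives were DESeq2 size factors, library size alone, no count filter, DESeq2 1.42.0 with its Wald test, the replicate number as a block, leaving out each library, the estimated correlation, a log2 limit of 1 for shared calls and leaving out the most counted fragment. Added after seeing the data were sums over isoacceptors, RIP without Acsl6, leaving out WT replicate 1 in the fragment groups and shares, and permutation within both experiments.

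Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 1.82 to 35.5 over 18 pairs. Intervals and floors, with 3 counts as the floor, cover counting error alone, and list medians were the same with members at 3 counts or fewer set at their bound. The tests were checked on simulated counts with known changes. The CLIP test recovered 61.2% of 2-fold and 93.8% of 4-fold changes over 9380 features, the RIP test 10.8% and 72.1% over 1788. The fragment tests recovered, in experiment 1, 71.6% and 100% over 575, in experiment 2 80.6% and 100% over 479 and in both experiments 89.7% and 100% over 651. A 2-fold change in RIP was mostly out of reach.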

Results

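The series asked which RNAs TET2 contacts, which RNAs carry 5-hydroxymethylcytosine (hm5C), and how small RNAs derived from tRNA change when Tet2 is lost, in mouse embryonic stem cells. TET2 is a dioxygenase that oxidises 5-methylcytosine to hm5C in DNA and in RNA. E14, the line used for the tagged clones, is a widely used mouse embryonic stem cell line, and the cells were grown with the GSK3 inhibitor CHIR99021 at 3 µM and the MEK inhibitor PD0325901 at 1 µM. In the crosslinking and immunoprecipitation (CLIP) part, 2 E14 clones carrying His-HA-tagged TET2, clone 65 and clone 75, were labelled with 4-thiouridine at 500 µM for 4 hours and irradiated with UVB at 400 mJ/cm2, and each clone gave 2 TET2 CLIP and 2 input libraries. In the RNA immunoprecipitation (RIP) part, RNA recovered with an antibody against hm5C gave 2 libraries, with 2 input libraries. In the small RNA part, RNA of 14 to 38 nt was sequenced from 3 WT and 3 Tet2 knockout cultures in experiment 1, and from 3 E14 and 3 Tet2 knockout cultures of another knockout set in experiment 2.

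Total counts were 2960450 to 4729463 in the CLIP inputs of clone 65, 913002 to 2277721 in those of clone 75, 221060 to 223413 in TET2 CLIP of clone 65 and 254996 to 453944 in TET2 CLIP of clone 75. RIP inputs held 4641963 to 4889943 counts and hm5C RIP libraries 1564014 to 2100187. The tRNA fragment (tRF) table held only tRNA-derived reads, with 104634 to 165669 counts in WT, 96070 to 137833 in the knockout of experiment 1, 110313 to 148719 in E14 and 130477 to 173450 in the knockout of experiment 2, so these sums are not the depth of the small RNA libraries.

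The CLIP comparison asked which RNAs were recovered with tagged TET2 above their level in the input. Nuclear tRNA genes, which encode the adaptors that bring amino acids to the ribosome, rose: 74 higher and 2 lower of 82 tested ones passed the test, with a median log2 change of 3.14. Of the 435 tRNA genes without an Ensembl name, 80 passed the count filter. Genes scarce in input passed it only where TET2 CLIP was high, so these values may overstate the rise. Over all 435, the share of counts rose by less, from 0.259% to 1.00% in clone 65 and 0.170% to 0.552% in clone 75 (means of n = 2). Spliceosomal snRNA genes, the RNA parts of the splicing machinery, rose as well (8 higher and 0 lower of 8, median 2.48), as did structured non-coding RNAs (8 higher and 0 lower of 9, median 2.31). Rmrp, the RNA of RNase MRP, reached 14297 ± 4802 against 575 ± 109.5 CPM (mean ± SD, n = 4 libraries each), a log2 change of 4.60 (SE 0.16). Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, rose by less (31 higher and 1 lower of 52, median 0.90), and genes of translation factors with a 5′ terminal oligopyrimidine (5′TOP) motif fell (1 higher and 6 lower of 18, median -0.43). In limma's camera these 2 lists reached adjusted p 4.69e-11 and 0.00313, calls lost with adjusted p = 0.0824 and 0.274 with an estimated correlation. Adjusted over the list alone, the counts were 77 higher and 3 lower for tRNAs, 8 higher and 0 lower for snRNAs, 8 higher and 1 lower for structured RNAs, 39 higher and 1 lower for histones and 1 higher and 8 lower for 5′TOP genes. In camera over 20 lists with a preset correlation of 0.01, adjusted p was 7.79e-60 for tRNAs, 2.12e-25 for snRNAs and 1.84e-20 for structured RNAs, and these 3 calls held (adjusted p = 0.0426, 0.0190 and 0.0118 with an estimated correlation).

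Among single tRNA genes, named by chromosome, number and anticodon, chr13.tRNA99-MetCAT was measured at 264 ± 193 against 3.56 ± 0.790 CPM and chr10.tRNA866-AspGTC at 258 ± 169 against 15.2 ± 3.67 CPM in TET2 CLIP and input (n = 4 each). Their log2 changes were 5.88 (SE 0.26) and 3.75 (SE 0.20). The glycine tRNA genes chr1.tRNA1012-GlyTCC and chr1.tRNA706-GlyGCC changed by 3.04 and 2.71. The U1 snRNA gene Rnu1b1 (chromosome 3, 96359953 to 96360117) rose from 230.02 ± 42.6 to 2321 ± 653 CPM (log2 3.32, edgeR adjusted p 2.81e-18), its copies Rnu1b2 and Rnu1b6 by 2.49 and 2.68, and the minor spliceosome RNA Rnu12 by 2.35. Near-identical copies share reads, so values of single tRNA and U1 genes are uncertain. Rpph1, the RNA of RNase P, rose by 2.61, the vault RNA Vaultrc5 by 2.72 and the Y RNA Rny1 by 2.31. Called histone genes included Hist2h3c2 at 1.84, Hist1h4h at 1.76 (181 ± 109.5 against 44.8 ± 4.10 CPM) and Hist1h3g at 1.44. Of the 5′TOP genes, the elongation factor genes Eef2 and Eef1a1 changed by -0.82 and -0.77, and Rack1, a ribosome-bound scaffold, by -0.64.

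Over all 10334 tested features, 929 were higher and 602 lower in TET2 CLIP (edgeR, adjusted p under 0.05), and with library size alone as scaling the split was 808 higher and 922 lower. Among the rises with the smallest p was Col4a2, a chain of basement membrane collagen (chromosome 8, 11312805 to 11449287), at 1275 ± 646 against 26.4 ± 8.94 CPM and log2 5.49 (SE 0.15). Next came Hsf1, the heat shock transcription factor (chromosome 15, 76477362 to 76501155), at 4162 ± 2785 against 117 ± 19.5 CPM and log2 4.94 (SE 0.17). The receptor tyrosine kinase gene Ros1 (chromosome 10, 52044863 to 52195398) was at 363 ± 136 against 1.48 ± 0.973 CPM and log2 7.74 (SE 0.23). The magnesium transporter gene Nipa2 rose by 4.11, the zinc finger gene Plag1 by 4.18, and the snRNA genes Gm23966, Gm24018 and Gm25541 by 4.90, 4.16 and 3.70. Gm23849 rose by 3.92. On the lower side stood Gata3, a lineage transcription factor gene (chromosome 2, 9857078 to 9887953), at 17.0 ± 5.06 against 309 ± 156 CPM and log2 -4.06 (SE 0.25). Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462675), was at 3384 ± 267 against 16521 ± 6178 CPM and -2.22. Wtap, a subunit of the m6A methyltransferase complex, was at 87.9 ± 19.1 against 507 ± 58.8 CPM and -2.57. Zfp654, Ermap, Nos1, Gm14236 and Gm15564 changed by -3.26, -3.54, -2.62, -3.86 and -2.45, and the 5.8S rRNA gene n-R5-8s1 by -2.65. Tet2 itself (chromosome 3, 133463677 to 133545136) was at 349 ± 40.4 against 354 ± 11.01 CPM, log2 -0.01 (SE 0.12), and did not pass the test. Leaving out single libraries moved the lower count to 1053 and 1081 without replicate 1 and 2 of TET2 CLIP of clone 65 and 954 without replicate 2 of TET2 CLIP of clone 75.

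The miRNA genes of the CLIP data rose as a list (10 higher and 4 lower of 16, 11 higher and 4 lower adjusted over the list alone, median 1.74, camera adjusted p 0.00097), a call lost with adjusted p = 0.0824 with an estimated correlation. Camera called the rise in clone 65 (11 higher and 2 lower, adjusted p 5.52e-07) and not in clone 75 (6 higher and 3 lower, adjusted p 0.455). Of the 16 genes, 7 had 3 counts or fewer over all TET2 CLIP or all input libraries. Mir1983 stood at 75.8 ± 28.9 against 4.29 ± 1.74 CPM (log2 4.25) and Mir6236 at log2 1.38. Ribosomal protein genes counted 4 higher and 8 lower of 81 (4 higher and 10 lower adjusted over the list alone), with a median of 0.02 (-0.10 with library size alone), a mean of -0.04 and a downward camera sign at adjusted p 0.671. Rplp0 changed by -0.84. SnoRNA and scaRNA genes, guides of RNA modification, counted 3 higher and 7 lower of 29 (4 higher and 7 lower adjusted over the list alone; adjusted p 0.308), with Snord118 at 1.27, Snord49a at 1.65, Snora78 at -3.37 and Snord13 at -1.51. SnoRNA host genes counted 3 higher and 1 lower of 12 (4 higher and 1 lower adjusted over the list alone; adjusted p 0.201), with Snhg8 at 1.78 and Gas5 at 0.75. Nuclear-retained lncRNAs counted 3 higher and 2 lower of 9 (4 higher and 2 lower adjusted over the list alone; adjusted p 0.438). Malat1 was at -0.66 and Tsix at 1.09, the latter uncertain because Tsix overlaps Xist on the other strand and strand use in counting was not given in the sources used here. Mitochondrially encoded mRNAs counted 1 higher and 1 lower of 9 (1 higher and 1 lower adjusted over the list alone), with a median of 0.05 (-0.07 with library size alone) against a downward camera sign (adjusted p 0.758). Mitochondrial tRNAs counted 1 higher and 0 lower of 8 (2 higher and 2 lower adjusted over the list alone; adjusted p 0.758), with mt-Tl1 at 1.62. Of the 2 mitochondrial rRNAs, a list too short for camera, mt-Rnr2 changed by -0.86 and mt-Rnr1 by -0.04.

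Among cell-state and regulator lists in TET2 CLIP, pluripotency genes counted 2 higher and 1 lower of 22 (2 higher and 1 lower adjusted over the list alone; adjusted p 0.758). Genes of the primed and early lineage state counted 1 higher and 0 lower of 5 (1 higher and 0 lower adjusted over the list alone; adjusted p 0.872). Extraembryonic endoderm markers counted 1 higher and 3 lower of 6 (2 higher and 3 lower adjusted over the list alone), with a median of -0.53, a mean of 0.60 and an upward camera sign at adjusted p 0.872. Col4a2 was the higher member, and Sparc at -1.18, Lama1 at -0.86 and Lamc1 at -0.46 were the lower ones. Fibroblast markers counted 0 higher and 1 lower of 3 (0 higher and 1 lower adjusted over the list alone; adjusted p 0.671), with Fn1 at -0.51. Of the 2 trophoblast markers tested Gata3 was lower and Tfap2c was measured at 0.51. Of the 2-cell-like genes only Zscan4b was tested, at -0.14 (adjusted p 0.894). Genes of the TET and DNA methylation machinery counted 1 higher and 1 lower of 9 (1 higher and 1 lower adjusted over the list alone; adjusted p 0.758). Uhrf1 changed by -0.54, and Tet3 by 0.90, a call lost without replicate 1 of TET2 CLIP of clone 65 (0.66) or of clone 75 (0.63). Of 8 RNA cytosine methylation genes edgeR called 0 and DESeq2 0, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p 0.804). SR and hnRNP protein genes, splicing regulators, counted 4 higher and 4 lower of 31 (4 higher and 5 lower adjusted over the list alone; adjusted p 0.804), with Hnrnpa3 at 1.63. Reference genes counted 1 higher and 0 lower of 9 (1 higher and 1 lower adjusted over the list alone; adjusted p 0.758). No endogenous retrovirus or LINE repeat entered the test.

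**Figure D1:**
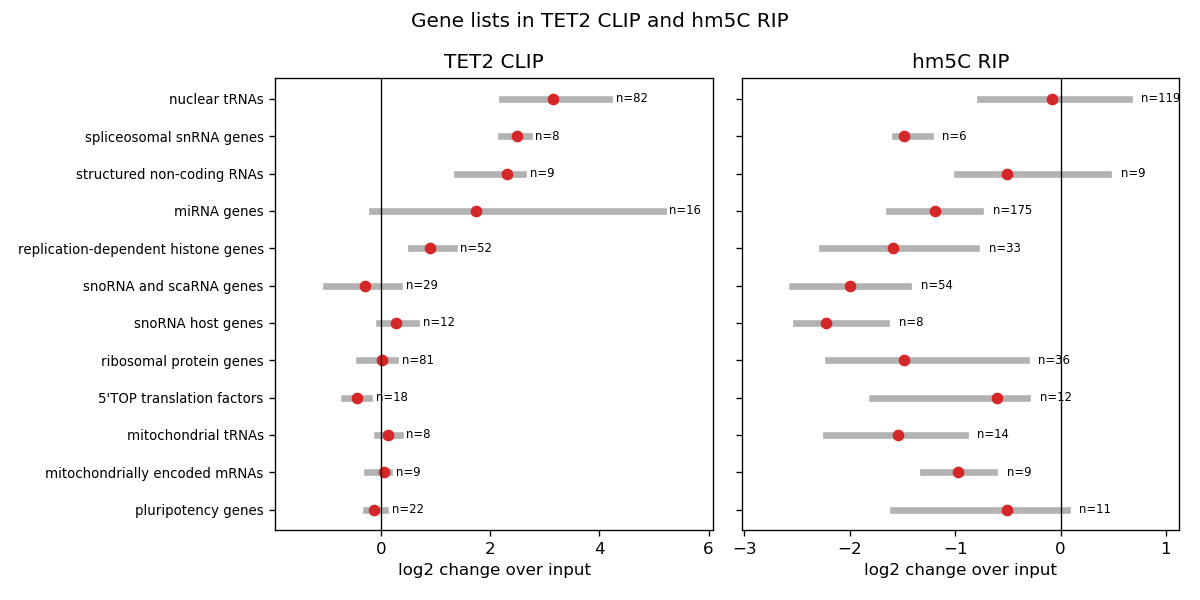
Median log2 change of the gene lists in TET2 CLIP against input and in hm5C RIP against input, with bars from the lower to the upper quartile of the members and the number of tested members beside each list. Nuclear tRNAs had a median of 3.14 in TET2 CLIP and -0.08 in hm5C RIP (0.11 with library size alone), and snoRNA and scaRNA genes -0.29 and -1.999. With Acsl6 left out and library size alone, these hm5C RIP medians were 1.42 and -0.53. The CLIP and RIP inputs held unlike RNA pools, so the 2 panels are not like for like.

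Both clones recovered nuclear tRNAs and snRNAs above input. In clone 65 nuclear tRNAs counted 68 higher and 1 lower with a median of 4.03, and in clone 75 57 higher and 2 lower with a median of 2.56. Camera adjusted p was 3.94e-65 and 4.64e-34, and the second call was lost, with adjusted p = 0.00880 in clone 65 and 0.0694 in clone 75 with an estimated correlation. Adjusted over the list alone, tRNAs counted 76 higher and 2 lower in clone 65 and 68 and 3 in clone 75. Spliceosomal snRNA genes counted 8 higher in clone 65 and 7 in clone 75 of 8, with medians of 3.04 and 1.82. Histone genes counted 38 higher and 0 lower in clone 65 (median 1.38) and 4 higher and 1 lower in clone 75 (median 0.44). In camera histone genes reached adjusted p 2.1e-14 in clone 65 and 0.129 in clone 75. The 5′TOP genes reached 0.140 in clone 65 and 0.000675 in clone 75, a call lost with adjusted p = 0.246 with an estimated correlation. Over all features, clone 65 had 848 higher and 297 lower and clone 75 had 643 higher and 406 lower. The clones shared 404 higher features against 52.8 for independent lists, and 122 lower features against 11.7, from separate libraries. With library size alone the split was 684 higher and 1326 lower in clone 65 and 872 and 264 in clone 75, with median shifts of all features of -0.41 and 0.16. Single libraries moved the higher count of clone 65 to 558 and 563 without replicate 1 and 2 of CLIP input of clone 65. They moved its lower count to 178 without replicate 1 of CLIP input of clone 65 and 617 and 612 without replicate 1 and 2 of TET2 CLIP of clone 75. They moved the higher count of clone 75 to 378 and 390 without replicate 1 and 2 of CLIP input of clone 65, 378 and 276 without replicate 1 and 2 of CLIP input of clone 75 and 340 without replicate 1 of TET2 CLIP of clone 75. They moved its lower count to 747 and 757 without replicate 1 and 2 of TET2 CLIP of clone 65, 206 without replicate 2 of CLIP input of clone 75 and 245 without replicate 1 of TET2 CLIP of clone 75. An untagged or antibody-only control was not analysed here, so recovery was measured against input alone.

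The hm5C RIP comparison asked which RNAs the hm5C antibody recovered above input. Acsl6, a long-chain acyl-CoA synthetase gene (chromosome 11, 54303805 to 54364756) chosen after its values were seen, took 57.9 ± 3.84% of all counts in hm5C RIP and 0.211 ± 0.0619% in input (mean ± SD, n = 2 each). Neurl3, an E3 ubiquitin ligase gene (chromosome 1, 36264602 to 36274674), rose from 1.36 ± 0.125 to 1608 ± 749 CPM, a log2 change of 10.17 (SE 0.56, edgeR adjusted p 1.99e-05). Aldh2, the mitochondrial aldehyde dehydrogenase gene (chromosome 5, 121566027 to 121593824), was at 952 ± 157 against 4.75 ± 0.205 CPM (log2 7.63). SnoRNA and scaRNA genes fell (0 higher and 49 lower of 54, median -1.999), and miRNA genes fell (5 higher and 108 lower of 175, median -1.19), a median that turned to 0.29 with Acsl6 left out and library size alone as scaling, while that of snoRNA and scaRNA genes was -0.53. Both calls were lost, with adjusted p = 0.388 and 0.389 with an estimated correlation. Nuclear tRNA genes went both ways (23 higher and 22 lower of 119, median -0.08, 0.11 with library size alone), but with Acsl6 left out and library size alone they counted 84 higher and 3 lower of 130 (median 1.42).

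Over all 2081 tested features 686 were higher and 394 lower in hm5C RIP. The receptor kinase gene Flt3 was at 737 ± 29.7 against 3.00 ± 1.24 CPM (log2 7.94), Mbp, a myelin protein gene, at log2 8.33, and the sodium pump subunit gene Atp1a4 at 8.86. Bicra, Nol4l, Hivep1, Duox2 and Odf2 rose by 8.32, 8.03, 7.32, 7.13 and 6.83. Among the falls with the smallest p was Eif5, a translation initiation factor gene, at 47.7 ± 20.5 against 754 ± 99.2 CPM (log2 -4.00, SE 0.38). Snord87 was at -3.73, the histone gene Hist1h4d at -2.97, mt-Ta at -2.80. Values were lower too for Gm26175, Gm26225, Gm22748, Gm25291, Gm25835 and Gm25117 at -4.66, -4.36, -3.22, -3.20, -3.18 and -3.06. The snoRNA Snord83b (chromosome 15, 80078503 to 80078579), stood at 8078 ± 1653 against 49033 ± 6099 CPM (log2 -2.60). With Acsl6 left out, a choice made after seeing the data, library size alone called 1686 higher and 88 lower of 2523, a median shift of all features of 1.47 log2, while TMM called 824 and 455 (shift -0.15). With n = 2 against 2, leaving out single libraries moved the higher count to 356 and 336 without replicate 1 and 2 of RIP input and the lower count to 640 without replicate 1 of hm5C RIP.

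In camera over 15 lists, 9 fell relative to the other features. Under an estimated correlation none of the 9 calls held, with adjusted p = 0.388 for snoRNA and scaRNA, ribosomal protein, histone, mitochondrial tRNA, snoRNA host and 5′TOP genes, 0.389 for miRNA genes and mitochondrially encoded mRNAs and 0.392 for snRNA genes with an estimated correlation. Of the 15 lists, 0 passed at an unadjusted p under 0.05. With the preset correlation, snoRNA and scaRNA genes reached adjusted p 8.47e-18 and miRNA genes 9.47e-14. Ribosomal protein genes counted 0 higher and 18 lower of 36, with a median of -1.49 that turned to 0.06 with Acsl6 left out and library size alone (adjusted p 1.84e-05), among them Rpl21 at -2.89. Histone genes counted 0 higher and 14 lower of 33, with a median of -1.59 that was -0.16 under that scaling (adjusted p 3.11e-05), with Hist1h4a at -3.64. SnoRNA host genes counted 0 higher and 6 lower of 8, with a median of -2.22 that was -0.78 (adjusted p 0.000784), with Gas5 at -2.50. Mitochondrial tRNAs counted 0 higher and 10 lower of 14, with a median of -1.54 that turned to 0.09 under that scaling (adjusted p 0.000139). Mitochondrially encoded mRNAs counted 0 higher and 4 lower of 9, with -0.97 that turned to 0.54 (adjusted p 0.0300). Spliceosomal snRNA genes counted 0 higher and 4 lower of 6, 0 higher and 0 lower of 5 under that scaling, with a median of -1.48 that was -0.09 there (adjusted p 0.0317 in the main test). That list was drawn by gene name, and here it also held Rnu3b3, a gene of the snoRNA U3, which is not spliceosomal. The 5′TOP genes counted 0 higher and 3 lower of 12, with a median of -0.61 that turned to 0.87 (adjusted p 0.0355). Adjusted over the list alone, miRNA genes counted 6 higher and 112 lower, nuclear tRNAs 21 higher and 17 lower and pluripotency genes 0 higher and 1 lower, and every other list tested by camera kept its count over all features.

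Single nuclear tRNA genes rose or fell in hm5C RIP. The gene chr13.tRNA83-LysTTT was at 60.4 ± 1.60 against 14.2 ± 0.823 CPM (log2 2.09, SE 0.27), chr1.tRNA485-LysTTT at 2.88 and chr13.tRNA972-TyrGTA at 5.07 with 6 input counts. By contrast, chr13.tRNA105-GluTTC was at 95.9 ± 4.25 against 453 ± 144 CPM (log2 -2.24). The tRNA list had a mean of 0.08 against its median of -0.08 and a downward camera sign at adjusted p 0.121. Structured RNAs counted 1 higher and 4 lower of 9 (adjusted p 0.199), with Rny1 at -1.47 and Rpph1 at -1.35, which were -0.01 and 0.15 with Acsl6 left out and library size alone. Nuclear-retained lncRNAs counted 1 higher and 2 lower of 4 (adjusted p 0.217), with Rian at -2.45. Pluripotency genes counted 0 higher and 2 lower of 11 (adjusted p 0.146), with Tfcp2l1 at -2.38. Under that scaling, structured RNAs counted 4 higher and 0 lower, nuclear-retained lncRNAs 2 and 1, and pluripotency genes 7 and 0. Of 3 TET and DNA methylation genes, 11 SR and hnRNP protein genes, 2 reference genes, 2 primed and early lineage genes and 1 RNA cytosine methylation gene, edgeR called 0, DESeq2 called 0 and 0 had an unadjusted p under 0.05. The SR and hnRNP list had a median of 0.39 and a mean of 0.35 against a downward camera sign (adjusted p 0.757), and the TET list reached adjusted p 0.998. Tet2 was at 4.09 ± 3.01 against 2.43 ± 1.38 CPM (log2 0.82, SE 0.70) and did not pass the test. Of lists too short for camera, mitochondrial rRNAs counted 1 lower of 2 (mt-Rnr2 at -1.05, 0.42 under that scaling), fibroblast markers 1 higher of 2 (Col1a2 at 3.56) and extraembryonic endoderm markers 1 higher of 2, and no 2-cell-like gene, trophoblast marker or repeat entered the test.

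**Figure D2:**
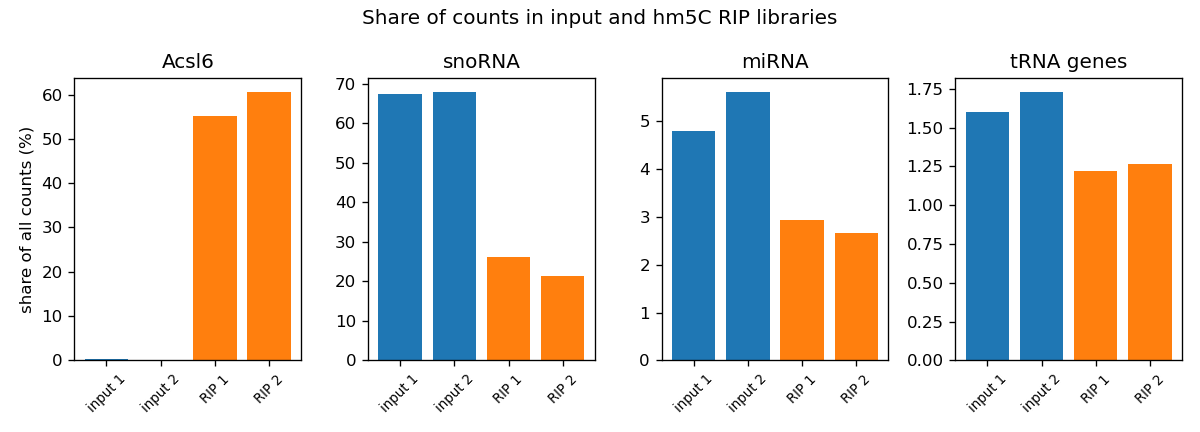
Share of all counts (%) taken by Acsl6 and by the snoRNA, miRNA and tRNA genes in each RIP input and hm5C RIP library, 1 bar per library. Acsl6 took 57.9% on average in hm5C RIP and 0.211% in input, and snoRNAs 23.7% and 67.6%.

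The CLIP and RIP inputs held unlike RNA pools. SnoRNA genes took 67.6% of counts in RIP input, against 0.296% and 0.308% in CLIP input of clones 65 and 75. Protein-coding genes took 8.34%, against 59.3% and 48.2% (means of n = 2). A comparison of the 2 parts is therefore not like for like. Whether the RNAs recovered with TET2 were also those recovered with the hm5C antibody was tested over the 1371 features tested in both. Among them 65 were higher in both, against 74.6 for independent lists (odds ratio 0.792, 95% confidence interval 0.571 to 1.09, 2-sided Fisher's exact p 0.145). Of 62 tRNA genes tested in both, 57 were higher in CLIP and 13 in RIP. All 13 were among the 57, but with so few left outside them this count cannot show an excess. The shared tRNA genes included chr1.tRNA706-GlyGCC, at log2 2.71 in CLIP and 1.38 in RIP, and chr11.tRNA1911-LeuCAA, at 3.13 and 3.39. Many of the 65 were 5S rRNA genes, such as n-R5s1 at 2.75 and 1.70 and n-R5s28 at 1.86 and 2.21. Near-identical copies share reads, and Fisher's exact test counted them separately. A rise in both does not show that the same molecules were bound and modified.

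The small RNA comparison asked how tRNA fragments change without Tet2. The deposited table sorts them into 3 kinds, tRF5 (in common usage, fragments of the 5′ end) and tRF3a and tRF3b (shorter and longer fragments of the 3′ end). The tRF3a share of tRF reads was 28.3 ± 3.01% against 13.8 ± 5.18% in experiment 1 and 18.5 ± 2.39% against 13.2 ± 1.80% in experiment 2 (mean ± SD, n = 3 each, knockout against control). The tRF5 share was 51.5 ± 2.17% against 75.5 ± 8.53% and 78.6 ± 2.93% against 84.2 ± 2.44%. The tRF3b share was 20.2 ± 0.862% against 10.7 ± 3.45% in experiment 1 and 2.91 ± 0.607% against 2.59 ± 0.662% in experiment 2. The table holds tRNA fragments alone, so the loss of Tet2 could not be checked in these libraries. In 2-sided exact permutation tests of 3 against 3, where 0.1 is the smallest possible p, tRF3a gave 0.1 and 0.1, tRF3b 0.1 and 0.5, tRF5 0.1 and 0.2, and the tRF total 0.7 and 0.3. Permuting within both experiments together, a test added after seeing the data with a smallest possible p of 0.005, gave exact p 0.005 for tRF3a (mean difference 9.87 percentage points), 0.01 for tRF5, 0.025 for tRF3b and 0.73 for the total. WT replicate 1 stood apart from its group, and without it the tRF3a share of WT was 16.7 ± 1.37% (n = 2).

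**Figure D3:**
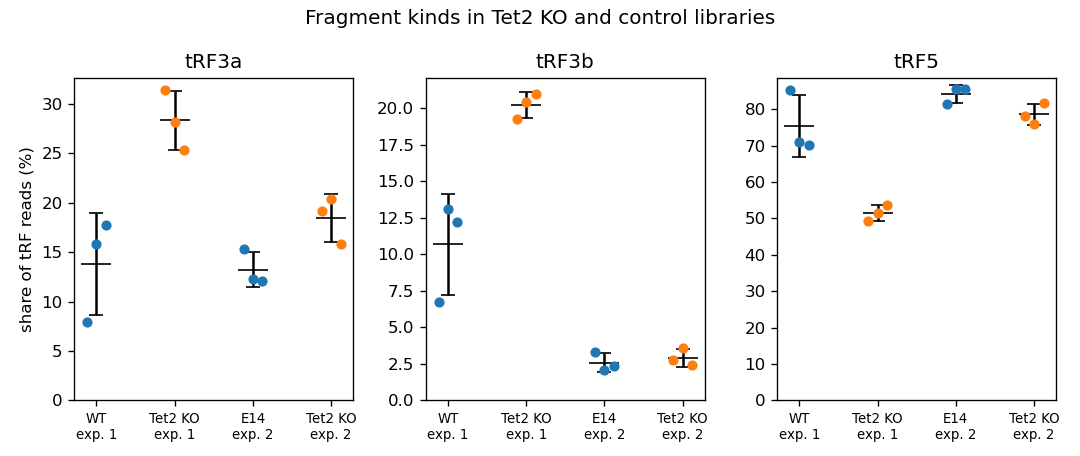
Share of tRF reads (%) of each fragment kind, 1 point per library, with the mean and SD of each group of 3, for both experiments. The tRF3a share averaged 28.3% in the knockout and 13.8% in WT in experiment 1, and 18.5% and 13.2% in experiment 2.

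In experiment 1, single leucine and serine tRF3a rose and single histidine tRF3a fell. The fragment chr13.tRNA65-LeuCAA tRF3a rose from 2198 ± 181 CPM in WT to 5453 ± 323 in the knockout (n = 3 each; log2 1.31, SE 0.18), and chr3.tRNA749-HisGTG tRF3a was at 98.5 ± 30.1 against 987 ± 257 CPM (log2 -3.30, SE 0.31). Fragments of leucine tRNAs counted 37 higher and 2 lower of 62 (median 0.81), serine 22 higher and 1 lower of 44 (0.63) and proline 20 higher and 0 lower of 42 (0.52). Histidine counted 0 higher and 10 lower of 18 (-1.67), glutamate 0 higher and 12 lower of 18 (-1.69), asparagine 0 higher and 9 lower of 12 (-1.28) and glycine 2 higher and 18 lower of 51 (-0.67). By kind, tRF3a counted 83 higher and 16 lower of 184 (median 0.61), tRF3b 41 higher and 4 lower of 184 (0.45) and tRF5 3 higher and 80 lower of 230 (-0.76). All 18 glutamate fragments were tRF5, as were 11 of the 12 asparagine fragments and all 9 lower ones. Their falls cannot be told apart from that of the kind.

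Other fragments rose in experiment 1, with chr10.tRNA698-SerCGA tRF3a at 1908 ± 128 against 867 ± 105 CPM (log2 1.14). Next were chr8.tRNA1013-LeuCAG tRF3a at 1.42, chr7.tRNA561-LeuAAG tRF3a at 1.62, chr14.tRNA709-LeuTAG tRF3a at 1.58 and chr11.tRNA205-GlyACC tRF3a at 1.05. Of the tRF5 kind, chr1.tRNA702-GlyGCC, chr13.tRNA1008-ThrAGT and chr3.tRNA749-HisGTG changed by -1.07, -1.36 and -1.18, calls lost with library size alone. Because copies share reads, counts were also summed over the genes of an isoacceptor, an alternative added after seeing the data. By kind, these sums counted 20 higher and 9 lower of 44 for tRF3a (median 0.32), a more mixed direction than by single fragments. For tRF3b they counted 14 higher and 1 lower of 45 (0.36), and for tRF5 1 higher and 18 lower of 46 (-0.55). HisGTG tRF3a was then at 393 ± 13.6 against 2977 ± 630.3 CPM (log2 -2.92, SE 0.19, edgeR adjusted p 4.63e-09). LysCTT tRF3a was at -2.87, AsnGTT tRF3a at -3.83 and LeuCAA tRF3a at 1.32. In experiment 2 these 3 were at 0.12 (edgeR adjusted p 0.818), -0.05 (0.934) and 0.72 (0.0321), and HisGTG tRF3a was not tested, so these falls were not seen again there. In camera over 68 groups, adjusted p was 2.02e-05 for tRF3a, 2.98e-06 for tRF3b, 8.83e-22 for tRF5, 2.26e-07 for leucine and 4.97e-06 for serine, 0.000108 for proline, 1.29e-08 for histidine, 1.72e-07 for glutamate, 0.000116 for asparagine and 0.00026 for glycine. No group was called with an estimated correlation, where 7 upward and 5 downward groups had an unadjusted p under 0.05. The values were adjusted p = 0.568, 0.291 and 0.263 for the 3 kinds, 0.249 for leucine, serine, histidine and asparagine, 0.258 for proline and 0.394 for glutamate and glycine with an estimated correlation.

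Fragments of the tRNAs methylated by Trdmt1, a tRNA cytosine methyltransferase, fell in experiment 1 (6 higher and 30 lower of 69, median -0.67, adjusted p 0.00155, lost with adjusted p = 0.394 with an estimated correlation). Fragments of tRNAs that prime retroviral reverse transcription rose (60 higher and 14 lower of 179, median 0.44, adjusted p 0.0003, lost with adjusted p = 0.249 with an estimated correlation). That list takes in all leucine, proline and glutamine tRNAs, and most of the 60 rises were the leucine and proline fragments given above. The primer tRNA LysTTT went the other way, with 6 of 6 tRF3a and 6 of 9 tRF5 lower and 0 of 9 tRF3b called. A rise of primer tRNA fragments as such is therefore not shown. Of the 30 lower Trdmt1 fragments, 29 were tRF5, a kind lower in general: AspGTC 12 of 15, GlyGCC 13 of 14 and ValAAC 4 of 7. ValAAC tRF3a went the other way, with 6 of 7 higher. Adjusted over the list alone, experiment 1 counted 89 higher and 22 lower for tRF3a, 24 higher and 2 lower for tRF3b, 2 higher and 76 lower for tRF5. By amino acid these counts were 37 higher and 2 lower for leucine, 29 higher and 3 lower for serine, 21 higher and 0 lower for proline, 1 higher and 17 lower for histidine, 0 higher and 18 lower for glutamate, 0 higher and 10 lower for asparagine, 2 higher and 18 lower for glycine. They were 8 higher and 32 lower for Trdmt1 substrates and 61 higher and 14 lower for primer tRNAs. Over all 598 tested fragments 127 were higher and 100 lower. The split was 166 to 51 with library size alone, 105 to 116 with DESeq2 size factors and 98 to 139 in DESeq2's own test, with median shifts of 0.44 and -0.11 log2 for the first 2. Single libraries moved the lower count to 166 without replicate 1 of WT and 40, 30 and 45 without replicate 1, 2 and 3 of the Tet2 knockout of experiment 1.

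In experiment 2, single leucine and proline tRF3a rose and single histidine tRF5 fell. The fragment chr11.tRNA1911-LeuCAA tRF3a was at 3897 ± 912 against 1974 ± 451 CPM in knockout and E14 (n = 3 each; log2 0.98, SE 0.17). The values of chr13.tRNA969-ProAGG tRF3a were 1022 ± 171 against 504 ± 46.4 CPM (log2 1.02, SE 0.24) and of chr3.tRNA749-HisGTG tRF5 2022 ± 268 against 3405 ± 113 CPM (log2 -0.75, SE 0.18). Proline fragments counted 15 higher and 0 lower of 29 (median 0.64), isoleucine 8 higher and 0 lower of 10 (0.85), leucine 7 higher and 1 lower of 45 (0.31), histidine 0 higher and 8 lower of 10 (-0.60) and glutamate 0 higher and 4 lower of 27 (-0.28). The isoleucine rises were all IleAAT tRF3a, which in experiment 1 counted 0 higher and 1 lower of 9 (median -0.62). Over both experiments edgeR called 0 of 28 isoleucine fragments. The histidine and glutamate falls were all tRF5. By kind, tRF3a counted 42 higher and 0 lower of 204 (median 0.31) and tRF5 6 higher and 27 lower of 187 (-0.18). Summed over isoacceptors, tRF3a counted 7 higher and 0 lower of 43 (median 0.12) and tRF5 1 higher and 6 lower of 45 (-0.25). Of 107 tRF3b fragments edgeR called 0 and DESeq2 0, with 4 lower at an unadjusted p under 0.05 (median 0.09, -0.02 with DESeq2 size factors, and a downward camera sign at adjusted p 0.619).

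Further rises in experiment 2 were chr13.tRNA65-LeuCAA tRF3a at 0.84, chr13.tRNA985-ArgACG tRF3a at 1.04 and chrX.tRNA636-AlaCGC tRF5 at 2.60. Further falls were chr4.tRNA622-AlaCGC tRF5 at -0.79 and chr2.tRNA587-HisGTG tRF5 at -0.62, the last lost without E14 replicate 2 (-0.52). Camera over 63 groups gave adjusted p 7.88e-15 for tRF3a, 1.61e-13 for tRF5, 3.83e-11 for proline, 1.01e-09 for histidine, 0.00015 for isoleucine, 0.000577 for glutamate and 0.0315 for leucine, all lost with adjusted p = 0.789 with an estimated correlation, where 1 upward and 0 downward groups had an unadjusted p under 0.05. Primer tRNA fragments counted 22 higher and 1 lower of 144 (median 0.29, adjusted p 0.00015, lost with adjusted p = 0.789 with an estimated correlation). All these calls were leucine and proline fragments, and 0 glutamine, lysine or phenylalanine fragments were called. Trdmt1 substrates counted 0 higher and 3 lower of 67, with a median of -0.07 (0.04 with library size alone) and adjusted p 0.0716. Adjusted over the list alone, experiment 2 counted 45 higher and 0 lower for tRF3a, 6 higher and 27 lower for tRF5. By amino acid these counts were 21 higher and 0 lower for proline, 9 higher and 0 lower for isoleucine, 7 higher and 1 lower for leucine, 0 higher and 9 lower for histidine, 0 higher and 4 lower for glutamate. They were 22 higher and 1 lower for primer tRNAs and 0 higher and 0 lower for Trdmt1 substrates. Over all 498 fragments 48 were higher and 27 lower, against 39 to 40 with DESeq2 size factors (median shift -0.11 log2) and 35 to 48 in DESeq2's own test. Single libraries moved the higher count to 30 without replicate 3 of E14 and 16 and 26 without replicate 1 and 2 of the Tet2 knockout of experiment 2. They moved the lower count to 52, 4 and 10 without replicate 1, 2 and 3 of E14 and 9 and 11 without replicate 1 and 2 of the Tet2 knockout of experiment 2.

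Across both experiments, 7 isoacceptor sums passed the test in each. LeuCAA tRF3a rose by 1.32 in experiment 1 and 0.72 in experiment 2, ProAGG tRF3a by 0.71 and 0.65, and ProTGG tRF3a by 0.76 and 0.74. ArgTCT tRF5 changed by -0.55 and -0.70, AlaCGC tRF5 by -0.57 and -0.69 and ValCAC tRF5 by -1.19 and -0.60. By contrast, GluCTC tRF3a went opposite ways, -2.15 and 0.95. The AlaCGC tRF5 sum passed narrowly in experiment 1 (edgeR adjusted p 0.0495), and its single fragments did not bear out a shared fall. They counted 1 higher and 0 lower of 3 in experiment 1 and 1 higher and 1 lower of 2 in experiment 2. The 3 shared rises and 3 shared falls compare with 2.12 and 1.34 for independent lists (Fisher's exact p 0.435 and 0.124). Among single fragments, 22 were higher in both against 11.6 (Fisher's exact p 0.00049) and 14 lower in both against 4.78 (p 2.27e-05), with copies that share reads counted separately and 2 called in opposite directions. In one model over the 12 libraries, 121 fragments were higher and 55 lower of 698. Isoacceptor sums in such a model counted 18 higher and 8 lower of 44 for tRF3a and 1 higher and 17 lower of 47 for tRF5. Among single fragments, histidine counted 0 higher and 6 lower of 18 (median -0.93) and leucine 28 higher and 2 lower of 67 (0.61). Proline counted 19 higher and 0 lower of 42 (0.60) and glutamate 0 higher and 17 lower of 27 (-0.43). Camera over 70 groups gave adjusted p 2.72e-06, 2.72e-06, 3.41e-10 and 7.25e-09, lost with adjusted p = 0.0693, 0.337, 0.337 and 0.337 with an estimated correlation. Adjusted over the list alone, these counted 0 higher and 12 lower, 31 higher and 2 lower, 20 higher and 0 lower and 0 higher and 17 lower. The split of the joint model was 116 to 87 in DESeq2's own test and 101 to 79 without the count filter. Single libraries moved the higher count to 78 without replicate 1 of the Tet2 knockout of experiment 2. They moved the lower count to 93 without replicate 1 of WT, 34 without replicate 1 of the Tet2 knockout of experiment 1 and 85 without replicate 3 of the Tet2 knockout of experiment 2. The experiments differed in library kit, control line and knockout set together, so these cannot be told apart.

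**Figure D4:**
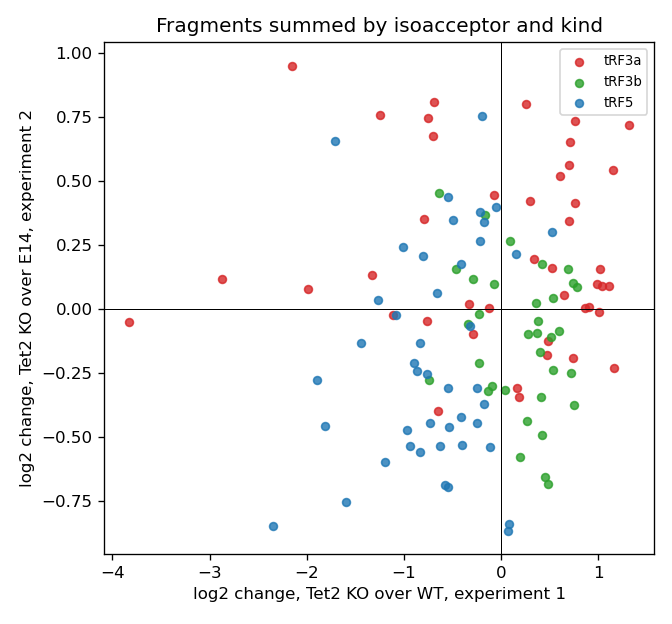
Log2 change, Tet2 knockout against control, of each isoacceptor sum in experiment 1 (x axis) and experiment 2 (y axis), 1 point per isoacceptor and fragment kind. LeuCAA tRF3a lies at 1.32 and 0.72, and HisGTG tRF5 at -1.60 (edgeR adjusted p 0.0739) and -0.76 (adjusted p 0.0321).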

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

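Chosen only after the result was seen were the tests without WT replicate 1, of the tRF3a to tRF3b ratio and of Acsl6, the permutation within both experiments and the fits without Acsl6.

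The enrichment over input differed between the 2 CLIP clones by a test of the difference itself (edgeR, adjusted p under 0.05). It was higher in clone 75 for 34 features and lower for 229. With library size alone the split was 638 to 104, a median shift of all features of 0.57 log2, so the balance of the counts rests on the scaling, and 102 of the 229 stayed called lower. Clone 75 minus clone 65, in log2, the structured and small RNAs were chr10.tRNA866-AspGTC at -2.24, mt-Tl1 at -1.28, mt-Tp at -1.27, Snord118 at -1.55, Vaultrc5 at -2.03, Rny1 at -1.93, Snord49a at -1.37, Rpph1 at -1.37, Mir6236 at -1.91 and Rmrp at -1.22. The spliceosomal RNAs were Rnu12 at -1.41, Gm25541 at -1.94, Rnu1b2 at -1.01, Gm23966 at -1.85, Gm24018 at -1.49 and Rnu1b1 at -1.10. The remaining genes were Plag1 at -1.16, Hsf1 at -1.99, Rps20 at -0.97, Ermap at -3.34, Nos1 at -2.17, Nipa2 at -1.37, Col4a2 at -2.17, Hist1h4h at -1.44, mt-Nd4l at -1.03, Gm15564 at -1.39 and Hist1h3g at -1.53, while Neat1 was at 0.92. Single libraries moved the higher count to 6 and 12 without replicate 1 and 2 of CLIP input of clone 65, 101 without replicate 2 of TET2 CLIP of clone 65, 4 without replicate 2 of CLIP input of clone 75 and 56 and 77 without replicate 1 and 2 of TET2 CLIP of clone 75. They moved the lower count to 119 and 111 without replicate 1 and 2 of CLIP input of clone 65 and 83 without replicate 2 of CLIP input of clone 75.

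The knockout effect on tRNA fragments differed between experiments by the same kind of test, higher in experiment 2 for 18 fragments and lower for 96. Experiment 2 minus experiment 1, in log2, leucine tRF3a were chr1.tRNA698-LeuCAG at -1.11, chr11.tRNA1911-LeuCAA at -0.96, chr13.tRNA1010-LeuCAA at -1.05, chr13.tRNA62-LeuAAG at -1.90, chr13.tRNA65-LeuCAA at -1.003, chr13.tRNA85-LeuCAA at -1.08, chr14.tRNA709-LeuTAG at -1.80, chr7.tRNA561-LeuAAG at -2.38, chr8.tRNA1013-LeuCAG at -1.16 and chr8.tRNA416-LeuCAG at -1.0002. Other tRF3a were chr10.tRNA698-SerCGA at -1.26, chr11.tRNA205-GlyACC at -1.34, chr13.tRNA112-SerTGA at -1.50 and chr13.tRNA88-SerAGA at -1.34, and tRF5 were chr13.tRNA1003-LeuTAA at 3.88, chr13.tRNA1008-ThrAGT at 1.46 and chrX.tRNA636-AlaCGC at 4.00. With library size alone the split was 14 to 1 (median shift 0.20 log2), with DESeq2 size factors 26 to 56 (0.23) and without the count filter 62 to 9 (0.50). Summed over isoacceptors it was 21 to 11. The balance of the counts thus rests on the processing. With library size alone, 12 of the 18 stayed called higher and 1 of the 96 lower, so nearly all tRF3a named here lost their call. Single libraries moved the higher count to 87 without replicate 1 of WT, 6 and 5 without replicate 2 and 3 of the Tet2 knockout of experiment 1 and 11 without replicate 2 of the Tet2 knockout of experiment 2. They moved the lower count to 24 without replicate 1 of WT, 1, 3 and 1 without replicate 1, 2 and 3 of E14 and 3, 1 and 2 without replicate 1, 2 and 3 of the Tet2 knockout of experiment 2. Kit, control line and knockout set changed together between the experiments, so a difference of any of them cannot be told apart from the others.

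Other splits of the same libraries bear on whether chance can be excluded. For CLIP over both clones, 1 of 18 splits, the real one, gave as many calls (1531, highest other 263), and 18 are too few for a share under 0.05. For experiments 1 and 2, 1 of 10 splits each gave as many (227 and 75, highest other 0 by edgeR in both). At an unadjusted p under 0.05 these others had 7 to 41 and 3 to 83 fragments, against 316 and 126 in the real splits. The 10 splits are too few for a share under 0.05. For both experiments together 2 of 100 drawn splits gave at least the real 176 calls, a share that excludes chance at 0.05 if neither experiment held an effect. The highest other, 229, kept experiment 1 as it was and exchanged E14 replicate 1 with knockout replicate 3 in experiment 2. For the difference of experiments 4 of 100 gave at least 114 (highest other 156). The others among these 4 kept experiment 1 and mixed experiment 2, so an effect in experiment 1 alone gives such counts, and the splits say nothing on chance for the difference.

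Rises in TET2 CLIP were weighed against 2 technical explanations. Small RNA genes lying inside the 345 higher protein-coding genes with coordinates could lend them reads. Of them 11.01% overlapped at least 1 (38 genes), against 10.3% of other genes matched for length (4172 small RNA genes, 408 of them nuclear tRNA genes; ratio 1.07, 95% confidence interval 0.739 to 1.41). For the 345 as a group, this argues against small RNA genes annotated in RefSeq as the whole cause. Small RNA copies without such an annotation were not counted, so reads from them stay open, as does the cause for any single gene. The lower depth of the TET2 CLIP libraries was tested by thinning every library to 221060 counts, where tRNA genes kept a median log2 change of 2.84 (37 of 40 higher). These 40 passed the same count filter, which favours genes high in TET2 CLIP, so that median may be too high. The share of counts on all tRNA genes, which needs no filter, also rose in both clones, so depth alone does not account for the tRNA rise. Binding of RNA to the beads or antibody without TET2 stays open, as a library without the tag was not analysed here. Contact with TET2 was not tested apart from it.

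In hm5C RIP, Acsl6 took most counts, which lowers the shares of the other features, so it was weighed for the falls alone. It stays open there, as 22.3% of 394 lower features (88, 95% confidence interval 18.3 to 26.8) were still called lower with Acsl6 left out and library size alone, against 97.2% (383) with TMM factors. Amplification of few molecules in a single library stays open. Of 46 features with 0 input counts and at least 20 counts in hm5C RIP replicate 1, 58.7% (27, interval 43.2 to 73.0) lay within 4-fold in replicate 2, and 9 were absent from it. Recovery without hm5C was not tested, since no antibody control was analysed here.

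The higher tRF3a share in Tet2 knockout cells could come from WT replicate 1, but 79.8% of the difference in experiment 1 was left without it. A fall of tRF5 reads alone stays open. It would move the tRF3a and tRF3b shares by 1 factor, and in experiment 1 these were 2.05 and 1.89 times those of WT (1.69 and 1.60 without WT replicate 1), a log2 change of their ratio of 0.14 (95% confidence interval -0.30 to 0.57), while in experiment 2 it was 0.30 (-0.08 to 0.69). Control line and knockout set stay open with Tet2 loss within each experiment. Permuting within both experiments gave exact p 0.005 for the tRF3a share, against 0.1, the smallest possible, in each experiment alone, and a biological effect of Tet2 remains a hypothesis.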

How the results depend on the processing

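Chosen only after the result was seen were the isoacceptor sums, the fits without Acsl6, the fragment groups without WT replicate 1 and the permutation within both experiments.

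Of values of single genes, fragments and lists, 3199 kept their side of the threshold under the alternatives fixed in advance, 211 lost the call and 56 gained it. Called values among the 3199 also kept their direction, while values called in neither setting were counted as kept even where their sign changed. Of counts and shares 190 stayed within 1.5 times or 1 SD and 87 moved. Under the added alternatives 357 were kept in this sense, 21 lost and 17 gained the call and 9 reversed. Of counts and shares 67 stayed and 9 moved. For the values that changed, the cause was not tested unless said here.

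With library size alone, lower calls were 922 in CLIP of both clones (602 with TMM), 1326 in clone 65 (297), 264 in clone 75 (406) and 51 in fragment experiment 1 (100). The clone difference gave 638 higher and 104 lower (34 and 229), and the experiment difference 1 lower (96). Size factors of DESeq2 gave 56 lower for the experiment difference. Without the count filter, lower calls were 1871 in CLIP of both clones and 1126 in clone 65, the clone difference gave 59 higher and 141 lower and the experiment difference 62 higher and 9 lower. The median of all features shifted by -0.13 with library size alone and -0.36 without the filter in CLIP of both clones. It shifted by -0.47, -0.25 and 0.22 without the filter in clone 65, clone 75 and their difference, and by 0.21 and -0.62 in RIP (library size alone, then no filter). It shifted by 0.13 without the filter in experiment 1, by 0.12 with library size in experiment 2, and by 0.14 and -0.11 in both experiments (in the same order). DESeq2's Wald test gave 189 lower in clone 65, 87 in both fragment experiments and 48 in experiment 2.

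Sums over isoacceptors, with fewer features tested, gave 35 higher and 28 lower in experiment 1, 8 and 6 in experiment 2, 22 and 26 in both and 21 and 11 for the difference. RIP without Acsl6 and with library size alone gave 1686 higher and 88 lower. This reversed, in log2, mt-Nd5 to 0.54, mt-Nd2 to 0.16, mt-Nd4l to 0.25, mt-Rnr2 to 0.42, mt-Rnr1 to 0.97, Rnu5g to 0.30, Rpph1 to 0.15, Rmrp to 0.54 and Hnrnpul2 to 1.02, a scaling that moves every log2 change up. With an estimated correlation, 3 lists were called higher and 0 lower in CLIP (5 and 1 with the preset one, camera of limma; 5 and 0 at an unadjusted p under 0.05). In RIP 0 were lower (9; 0 unadjusted). Of the fragment groups 0 higher and 0 lower were called in experiment 1 (17 and 16; 7 and 5 unadjusted), experiment 2 (14 and 6; 1 and 0 unadjusted) and both (12 and 16; 2 and 7 unadjusted). The odds ratio of shared CLIP and RIP rises, 0.792, was 0.928 with a log2 limit of 1, 0.813 with DESeq2 size factors and 0.908 with library size alone. Without WT replicate 1, 14 fragment groups were higher and 17 lower in experiment 1 and 11 and 15 in both.

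Leaving out single libraries, counts lay at 453 to 1081 lower in CLIP of both clones, 558 to 985 higher and 178 to 617 lower in clone 65. They lay at 276 to 645 and 206 to 757 in clone 75, 4 to 101 and 83 to 271 for their difference, 336 to 745 and 301 to 640 in RIP. They lay at 30 to 166 lower in fragment experiment 1, 16 to 51 and 4 to 52 in experiment 2, 78 to 130 and 34 to 93 in both and 5 to 87 and 1 to 98 for their difference. In RIP this left 1 library on a side, assumed to vary like the others. The tRF3a share difference ranged from 11.6 to 16.5 percentage points in experiment 1 and 4.24 to 6.55 in experiment 2. That of tRF3b ranged from 7.55 to 10.7 and from -0.02, without replicate 2 of the Tet2 knockout of experiment 2, to 0.69.

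Replicate numbers did not pair the libraries (correlations of deviations -0.00273 and 0.0123 in the CLIP clones, 0.0654 in RIP, -0.397, 0.0928 and -0.474 in experiment 1 and 0.0913, -0.344 and 0.253 in experiment 2). In neither experiment did every sample correlate best with its own number. With the replicate block, clone 75 had 382 higher and 264 lower, the clone difference 13 higher, experiment 1 61 lower and the experiment difference 7 higher. Alternatives planned for normalized values were not run because the files hold counts. Thinned to 221060 counts per library, 5059 CLIP features entered the test, against 10334 at full depth. The RIP test, with 2 against 2 libraries, recovered 10.8% of simulated 2-fold changes.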

Other observations

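Chosen only after the result was seen were the biotype classes reported here. In TET2 CLIP, genes of the snRNA biotype counted 158 higher and 0 lower of 167 (median log2 3.07; 162 and 1 adjusted over the list alone; camera adjusted p 3.43e-129, adjusted p = 0.0259 with an estimated correlation). The rRNA genes counted 15 higher and 1 lower of 18 (median log2 2.42; 15 and 1 adjusted over the list alone; camera adjusted p 1.5e-33, adjusted p = 0.0336 with an estimated correlation). The rRNA genes named above as higher in TET2 CLIP were near-identical copies of a single kind, and the one named of another kind was lower. Such copies share reads and were counted separately, and the estimated correlation of the list was 0.51. These rises are thus not independent, and they do not show that rRNA as a whole was recovered above input. Protein-coding genes counted 385 higher and 501 lower of 8672 (median log2 -0.07; 334 and 410 adjusted over the list alone; camera adjusted p 3.54e-19, adjusted p = 0.000162 with an estimated correlation). Their balance differed between the clones, with 354 higher and 253 lower in clone 65 and 229 and 315 in clone 75. The snRNA genes took 1.80% of counts in the input and 12.4% in TET2 CLIP of clone 65, and 2.03% and 8.71% in clone 75 (means of n = 2). The tRNA genes took 0.259% and 1.00% in clone 65 and 0.170% and 0.552% in clone 75. The rRNA genes took 0.768% and 0.996% in clone 65, and 0.990% and 0.934%, no rise, in clone 75. These values cover genes of the rRNA biotype alone. The single gene Gm26917, outside that biotype, took 22.7% of input and 18.2% of TET2 CLIP counts in clone 65, and 32.4% and 19.8% in clone 75. In hm5C RIP, snoRNA genes counted 2 higher and 88 lower of 106 (median log2 -2.02; 3 and 89 adjusted over the list alone; camera adjusted p 3.86e-23, adjusted p = 0.468 with an estimated correlation). Protein-coding genes counted 540 higher and 93 lower of 1369 (median log2 0.62; 533 and 86 adjusted over the list alone; camera adjusted p 6.94e-11, adjusted p = 0.0422 with an estimated correlation). Genes scarce in input passed the count filter only where hm5C RIP was high, so these values may overstate the rise. Over all RIP features, the split was 591 higher and 538 lower without that filter, against 686 and 394 with it. With Acsl6 left out, snoRNAs took 56.2% of hm5C RIP counts and 67.8% of input counts, snRNA genes 0.384% and 0.246%, and tRNA genes 2.97% and 1.67%. Protein-coding genes, taken without the filter, then held 15.9% of hm5C RIP counts and 8.15% of input counts.

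The most counted fragment, chr1.tRNA702-GlyGCC tRF5, had 29221 counts over the 12 small RNA libraries. WT replicate 1 differed from the other 2 WT replicates with a chi-square per degree of freedom of 33.6 and 35.5, against 3.29 between those.

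A hypothesis of this work was that tRNAs recovered more with TET2 or with the hm5C antibody change more in the knockout. Across isoacceptors, with experiments 1 and 2 in one model, Spearman's rho was 0.211 between the TET2 CLIP and tRF3a changes (30 isoacceptors), 0.179 between TET2 CLIP and tRF5 (33), 0.00646 between hm5C RIP and tRF3a (38) and 0.115 between hm5C RIP and tRF5 (41). Adjusted p over the 4 relations was 0.630, 0.630, 0.970 and 0.630 from 100000 2-sided permutations, and Pearson's r was 0.0461, 0.00931, 0.0481 and 0.0939 (adjusted p 0.959). These values leave the hypothesis undecided.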
